A study of Zea mays with 6 samples.

How the data were processed

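The data set comprised 6 RNA-seq libraries from leaves of the maize inbred line KN5585, 3 from non-transgenic control plants and 3 from plants carrying a transgene. Per the labels' protocols, libraries were made with a SMARTER mRNA-Seq kit from total RNA; whether strand was kept is not given in the sources used here. The authors deposited 1 table per library, with FPKM values (fragment numbers scaled to gene length and to the mapped fragments of the library) rounded to 2 decimals for 44351 genes, per the file headers. The submitters' processing notes name DESeq2 without a version or a role. They also name mm10, a mouse build, per the submitters' processing notes, whereas the identifiers in the tables are those of maize. The aligner, the counting program and the maize build are not given in the sources used here.

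FPKM removes read numbers, so the depth of each library is unknown and no counting interval was computed. The lowest values were searched for a common step: for 21 miRNA genes whose lowest values were up to 5 FPKM in both groups, the ratio of these values was taken, transgenic over control. Between ratios of 0.3 and 3, the fullest window of width 0.04 held 4 genes, at a median of 0.490. A narrower search from 0.7 to 1.4, made after that result was seen, gave 3 genes at 0.975. No ratio stood out in these searches. A lowest value can stand for more than 1 fragment, so neither ratio settles the relative depth, which was not derived. The lowest values above 0 of zma-mir156l, zma-mir167e and zma-mir169d were close: 1.39, 0.81 and 0.72 FPKM in control, 1.36, 0.79 and 0.70 FPKM in transgenic libraries. Those of other genes, such as zma-mir395o (0.96 and 0.31 FPKM), were not. FPKM is relative to the mapped fragments of each library, so genes that take a larger share lower the values of all others.

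The files hold 44146 identifiers that start with Zm00001d, 51 that start with GRMZM and 154 miRNA genes. The reference table, of assembly Zm-B73-REFERENCE-NAM-5.0, matched 0, 0 and 153 of these. No coordinates were taken from it. Before the data were examined, 35 lists of genes (sucrose synthases, invertases, sugar transport, starch and trehalose metabolism, abscisic acid, dehydrins, photosynthesis, cell type markers and others) had been fixed by symbol and description. None of the 35 lists had a member that could be named, so the planned tests of lists and of ZmSUS1 were not run. The rule for named genes, also fixed then, was the members of those lists and the genes with the largest changes among those past the threshold, not overlapping between groups and averaging at least 5 FPKM in the higher group. Without names, the 2 largest rises and the 2 largest falls are given by identifier. The miRNA genes were chosen for naming after their values were seen, as all such genes that could be tested.

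Genes with a mean of at least 0.5 FPKM over the 6 libraries (22944 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term, empirical Bayes moderation with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment; the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. No scaling between libraries was added to the deposited FPKM; because median-of-ratios scaling, computed on the FPKM, shifts the median of all genes, scaled values were also computed for every tested gene. Families of miRNA genes were tested with camera at a preset correlation of 0.01 as the main set test, with an estimated correlation, and with fry. Shares of abundant genes were compared with exact permutation tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

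The gene-wise test was tested on simulated data built from the control means and the residual spread of each of the 22944 genes, for the transgenic against control comparison. It recovered 35.8% of 67 genes changed 1.25-fold, 52.2% of 67 changed 1.5-fold and 75.8% of 66 changed 2-fold, with 2 false calls among 22744 unchanged genes. Of 200 unchanged sets of 9 genes, 5.5% had an unadjusted camera p below the threshold and 5% an unadjusted fry p. In the simulation few genes changed and their median was not shifted, whereas most genes differed in the data. The rates of recovery and of false calls may therefore not hold for the data.

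Both groups carry replicate numbers 1 to 3 in the labels. The deviations of same-numbered libraries from their group means correlated at 0.002, -0.05 and 0.002, and no label ties them, so the libraries were not treated as paired. The alternatives were another pseudocount (0.1), no filter or a minimum of 2 FPKM, 3 scalings between libraries, 2 variance models, the replicate number as a block, an adjusted p of 0.01 and leaving out each library.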

Results

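Gene expression in maize leaves was profiled by RNA sequencing in 2 groups of plants of KN5585, a maize inbred line used for transformation. One group carried a transgene and the other was its non-transgenic control, and each group had 3 libraries. The series title names ZmSUS1 as the overexpressed gene; sucrose synthase, the enzyme family of that name, cleaves sucrose reversibly into fructose and a nucleotide sugar. Both groups carry a drought time point in the labels, with a length of 3 days for each sample and of 5 days in the series text, but the treatment label of the control samples is normal and that of the other samples is transgenic. Whether the control plants were under drought is therefore taken from the time point and the series text; if they were not, each difference between the groups would include drought as well as the transgene. Each library held FPKM values for 44351 genes, so its depth in reads is unknown. Total FPKM was 685931 ± 3134 (SD, n = 3) in the control libraries and 830423 ± 794 (SD, n = 3) in the transgenic libraries. Genes with a value above 0 numbered 29298 ± 74 (SD, n = 3) in the control libraries and 28306 ± 7 (SD, n = 3) in the transgenic libraries.

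The comparison of the 2 groups asks which leaf transcripts differ between overexpressing and control plants, both read as being under drought. The level of ZmSUS1 itself and of genes of sucrose, starch, trehalose, abscisic acid and photosynthesis pathways was not analysed here, because the files carry identifiers that neither they nor the reference table used here pair with gene symbols. The genes that could be named were the miRNA genes, which the files list under their own names and which were chosen after their values were seen. Over all tested genes the median log2 difference between the groups was -0.56, so median-of-ratios scaling, which removes that shift, was also applied.

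Transcripts of miR156 genes were lower in the transgenic leaves. miR156 is a conserved plant miRNA that represses SPL transcription factors and maintains the juvenile phase. Summed over its 11 listed genes, the level was 320.5 ± 8.7 FPKM (SD, n = 3) in the control libraries and 62.7 ± 6.3 FPKM (SD, n = 3) in the transgenic libraries, a 5.11-fold difference, or 3.18-fold after median-of-ratios scaling. Of the 9 miR156 genes tested, 8 were lower past the threshold, 1 was not called and 0 were higher. Most genes were lower as deposited: of all 22944 tested, 15529 were lower past the threshold, and 8464 after median-of-ratios scaling. The count of lower members therefore does not by itself set the family apart. Against all other genes the family did not pass (camera adjusted p = 0.44, and 0.29 after scaling). The most abundant, zma-mir156d, fell from 168.2 ± 9.2 to 17.2 ± 3.2 FPKM (SD, n = 3 each), a log2 fold change of -3.23 ± 0.11 (SE, limma, Benjamini-Hochberg adjusted p = 2.3e-08), or -2.57 after scaling. The genes zma-mir156f, zma-mir156g and zma-mir156k fell by 2.90, 2.75 and 1.58 on the log2 scale, with limma adjusted p of 2.1e-05, 8.2e-06 and 4.5e-06. Their scaled log2 fold changes were -2.34, -2.14 and -0.92. After median-of-ratios scaling 5 of the 9 genes were still lower past the threshold, and zma-mir156e, zma-mir156h and zma-mir156i were not. These 3 genes stood at 19.0, 12.7 and 3.21 FPKM in the control libraries and at 10.1, 7.02 and 1.64 FPKM in the transgenic libraries. The 5 genes still called included zma-mir156a, which averaged only 1.11 FPKM in the control and 0.18 FPKM in the transgenic libraries.

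Genes of miR398, miR408 and miR528 were higher in the transgenic leaves. These miRNAs target transcripts of copper-containing proteins, among them Cu/Zn superoxide dismutases, laccases and plantacyanins. The gene zma-mir398b rose from 40.9 ± 3.0 to 89.8 ± 8.4 FPKM (SD, n = 3 each), a log2 fold change of 1.12 ± 0.07 (SE, limma adjusted p = 1.3e-06), or 1.79 after scaling. The genes zma-mir408b and zma-mir528a rose by 1.31 ± 0.11 and 1.79 ± 0.14 on the log2 scale (SE, limma adjusted p = 5.2e-06 and 3.7e-06), and by 1.95 and 2.43 after scaling. The gene zma-mir528b was listed at 0 in 2 of 3 control libraries and averaged 8.95 ± 4.83 FPKM (SD, n = 3) in the transgenic libraries (limma adjusted p = 0.0011, and 0.00043 after scaling). The remaining tested member, zma-mir398a, averaged 2.50 FPKM in the control and 5.09 FPKM in the transgenic libraries and did not pass the test (limma adjusted p = 0.085), but passed it after median-of-ratios scaling (limma adjusted p = 0.016).

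Other miRNA genes differed in both directions. The gene zma-mir169i, of a family that targets NF-YA transcription factors, rose from 5.75 ± 2.02 to 19.2 ± 4.1 FPKM (SD, n = 3 each; limma adjusted p = 0.00019), a log2 fold change of 1.61, or 2.21 after scaling. The gene zma-mir166d, of a family that targets HD-ZIP III transcription factors, was listed at 0 in every control library and at 4.03, 7.09 and 6.07 FPKM in the transgenic libraries (limma adjusted p = 7.8e-07, and 6.1e-07 after scaling). Both tested genes of miR168, which targets ARGONAUTE1 transcripts, were lower: zma-mir168b fell by 1.53 and zma-mir168a fell by 1.43 on the log2 scale (limma adjusted p = 1.9e-05 and 0.0021). After scaling their log2 fold changes were -0.91 and -0.81 (limma adjusted p = 0.00069 and 0.041). The gene zma-mir162, of a family that targets DICER-LIKE1 transcripts, fell by 1.98 on the log2 scale with a SE of 0.49 (limma adjusted p = 0.0050), and the scaled value was -1.53 (limma adjusted p = 0.029). The genes zma-mir159a and zma-mir396a were lower as deposited, at limma adjusted p = 0.0076 and 0.023. After median-of-ratios scaling neither passed the test, and the difference of zma-mir396a turned from -0.40 to 0.24. All of these values are FPKM of the miRNA genes in mRNA libraries, not of the mature miRNAs. Reads that family members or overlapping genes share cannot be told apart in them. The low values, such as those of zma-mir156a, zma-mir166d and zma-mir528b, may rest on few fragments, whose number was not derived. In the transgenic libraries zma-mir169d, for example, stood at 0.70, 1.41 and 2.82 FPKM, near multiples of a common step. The values of zma-mir156a were 1.10, 1.11 and 1.11 FPKM in the control and 0.54, 0 and 0 FPKM in the transgenic libraries. Equal small fragment numbers would give such a small control spread, so its tests may overstate certainty. The limma tests hold no term for counting error.

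**Figure D1:**
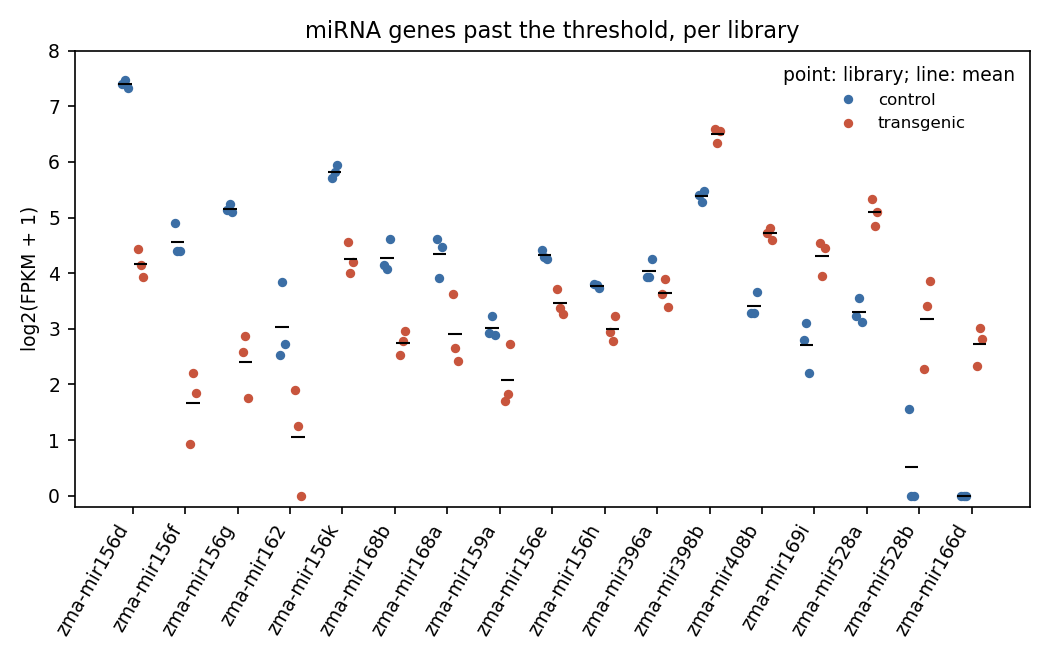
Level of 17 miRNA genes in each library, as log2(FPKM + 1), ordered by log2 fold change; points are libraries, lines are group means, and genes shown passed the threshold, did not overlap between groups and averaged at least 5 FPKM in the higher group. The gene zma-mir156d drops from a mean of 168.2 to 17.2 FPKM, and zma-mir528a climbs from 8.98 to 33.6 FPKM; after median-of-ratios scaling zma-mir156e, zma-mir156h, zma-mir159a and zma-mir396a no longer pass, and zma-mir396a turns from -0.40 to 0.24.

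Of 36 miRNA genes tested, 8 were higher, 14 were lower and 14 did not pass the threshold (limma). After median-of-ratios scaling the counts were 11 higher, 9 lower and 16 not called. Of all tested genes 84.0% were called as deposited and 73.2% after scaling, so miRNA genes were called less often than genes at large. Families of at least 2 tested genes were compared as sets, a choice made after the data were examined. With camera, the main set test, which sets a family against all other genes, 0 of 10 families passed, and 4 had an unadjusted p below the threshold. They were miR166, miR169, miR398 and miR528, all up, with camera adjusted p of 0.10, 0.071, 0.071 and 0.071. The same 4 families passed camera when libraries were scaled to the same total FPKM. The adjusted p of miR156 was 0.44 with camera, 0.29 after median-of-ratios scaling, and 0.55 as deposited with an estimated correlation; with estimated correlations 0 families passed. With fry, which tests whether the genes of a set move on balance one way, 6 of 10 families passed the threshold, and 7 of 10 after median-of-ratios scaling. The miR156, miR168 and miR395 families moved down (fry adjusted p = 7.9e-05, 0.0019 and 0.0073) and the miR166, miR398 and miR528 families moved up (fry adjusted p = 0.00027, 0.0055 and 0.00075). In each of miR166, miR395 and miR398 only 1 of the 2 tested genes was called as deposited; the uncalled gene of miR166, zma-mir166c, had a limma adjusted p of 0.72. The direction from camera was up and that from fry and the mean was down for miR159, miR167 and miR396, none of which passed either test.

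In the whole transcriptome, expression was more concentrated in a few genes in the transgenic leaves. The 100 most abundant genes of each library held 24.7% ± 0.04 (SD, n = 3) of the summed FPKM in the control libraries and 48.8% ± 0.23 (SD, n = 3) in the transgenic libraries. The 10 most abundant held 8.28% ± 0.06 and 13.2% ± 0.15, and the 1000 most abundant 50.6% ± 0.07 and 71.8% ± 0.16. All 3 transgenic libraries lay outside the range of the controls in each of these shares (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give). The 100 most abundant genes of the 2 groups had 67 genes in common. Of the 100 most abundant in the transgenic leaves, 92 were higher there than in the control and 6 were lower. Being chosen for their transgenic level favours that direction.

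**Figure D2:**
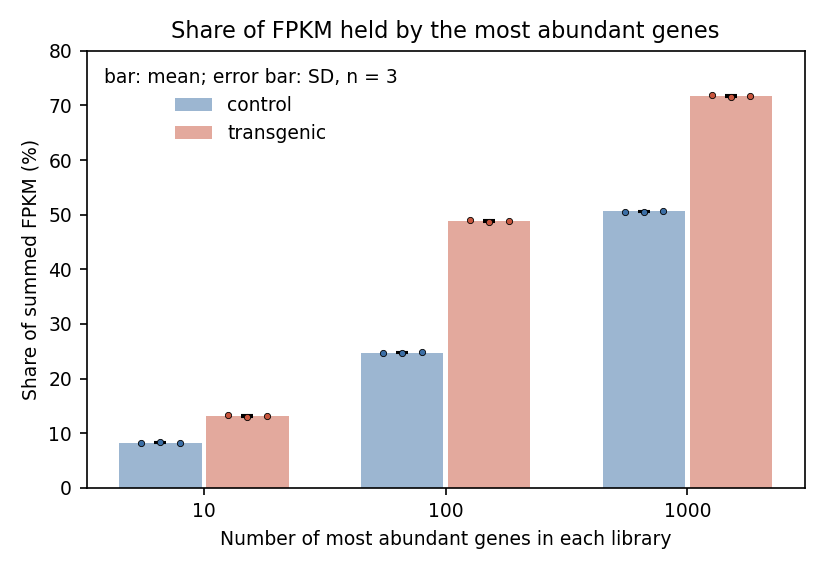
Share of each library's summed FPKM, in percent, held by its 10, 100 and 1000 most abundant genes; bars are group means, error bars the SD of 3 libraries, points the libraries. The share of the 100 most abundant genes stands at 24.7% in the control and 48.8% in the transgenic libraries.

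A large part of the transcriptome differed between the groups. Of 22944 genes tested, 19278 passed an adjusted p of 0.05 (limma on log2(FPKM + 1), Benjamini-Hochberg), 3749 higher and 15529 lower in the transgenic leaves. Of these, 6691 differed by at least 1 on the log2 scale, 1276 higher and 5415 lower; after median-of-ratios scaling 4440 did, 2693 higher and 1747 lower. The values of the groups as deposited did not overlap in 84.5% of the genes tested, where chance gives 10%. A shift shared by most genes raises this share by itself, and the share was not computed after scaling. The median log2 difference over all tested genes, -0.56 as deposited, was -0.02 after median-of-ratios scaling. The calls then numbered 16797, of which 8333 were higher and 8464 lower. Thus the share of lower genes among the calls was 80.6% as deposited and 50.4% after scaling. In the same direction under both scalings 12213 genes passed, and 2295 passed in opposite directions. For genes close to the median shift the direction therefore holds only relative to the deposited FPKM totals.

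**Figure D3:**
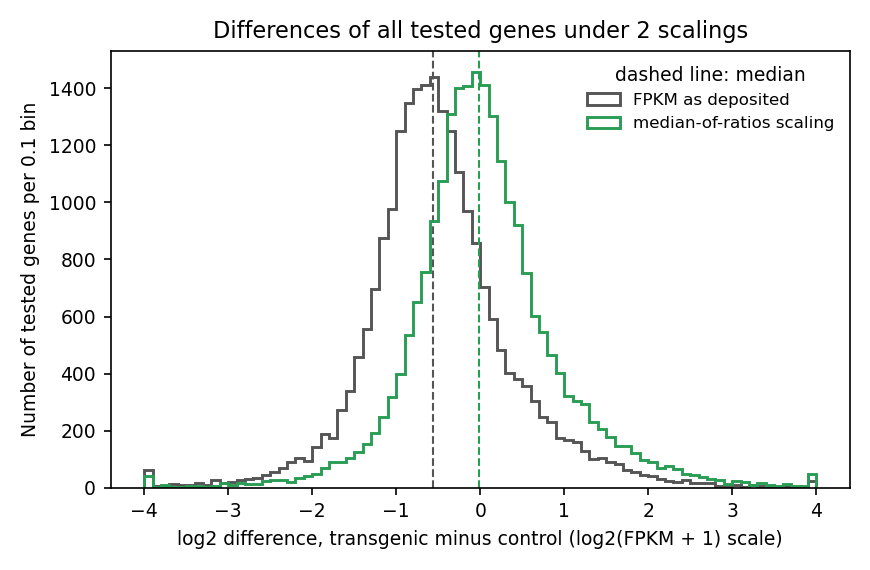
Number of tested genes by log2 difference, transgenic minus control on the log2(FPKM + 1) scale, in bins of 0.1, with values beyond 4 in either direction placed in the end bins. The median, a dashed line, lies at -0.56 for FPKM as deposited and at -0.02 after median-of-ratios scaling.

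The direction of change varied with abundance. Of the 152 genes with a mean of at least 500 FPKM over all libraries, 119 were higher and 29 lower in the transgenic leaves, with a median log2 difference of 1.35. Among the 1967 genes with a mean from 50 to 500 FPKM, 721 were higher and 1121 lower, with a median of -0.29. Among the 11894 genes from 5 to 50 FPKM, 1618 were higher and 9162 lower, with a median of -0.66, and among the 8931 genes from 0.5 to 5 FPKM, 1291 were higher and 5217 lower, with a median of -0.46. After median-of-ratios scaling 136 were higher and 15 lower in the most abundant class, and the class from 50 to 500 FPKM turned to 1258 higher and 572 lower. The counts were then 4470 higher and 4852 lower from 5 to 50 FPKM, and 2469 higher and 3025 lower from 0.5 to 5 FPKM. Genes can enter the most abundant class by a high level in either group alone, so the classes are not independent of the difference.

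The largest changes were in genes without a symbol in the files. Zm00001d044396 rose from 0.313 ± 0.241 to 318.4 ± 52.8 FPKM (SD, n = 3 each), a log2 fold change of 7.93 ± 0.15 (SE, limma adjusted p = 7.2e-10). With a pseudocount of 0.1 its log2 fold change was 9.73, so the size depends on the pseudocount. Zm00001d044399 rose 104.7-fold, from 74.9 ± 8.2 to 7846 ± 53 FPKM (limma adjusted p = 1.5e-11). Zm00001d037894 dropped from 1372 ± 65 to 2.88 ± 0.38 FPKM and Zm00001d028750 from 819.7 ± 10.2 to 5.52 ± 0.16 FPKM (limma adjusted p = 7.5e-12 and 7.8e-13). After median-of-ratios scaling the log2 fold changes of Zm00001d044396, Zm00001d044399, Zm00001d037894 and Zm00001d028750 were 8.33, 7.38, -7.87 and -6.34. Of all 44351 genes, 43 were listed at 0 in every control library and averaged at least 1 FPKM in the transgenic libraries. They included zma-mir166d, and also zma-mir397b, whose transgenic values were 0, 0 and 4.77 FPKM. The opposite held for 93 genes. Among the tested genes, 106 shared all 6 values with another gene, in 43 sets, so their levels cannot be assigned to single genes.

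The spread between libraries of a group was small. Pearson's r across genes, which are not independent replicates, on the FPKM scale ranged from 0.99946 to 0.99983 within groups and from 0.776 to 0.788 between groups. On the log2(FPKM + 1) scale, the one tested, it ranged from 0.9946 to 0.9952 within groups and from 0.940 to 0.941 between groups. For genes of at least 500 FPKM the median coefficient of variation was 1.52% in the control and 1.10% in the transgenic libraries. The series calls the libraries biological replicates, and the labels do not say whether they came from separate plants. The p-values measure only the spread between these libraries, whether biological or technical.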

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

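The tests of the median shift and of the miRNA families were chosen after the results were seen. The count of changed genes, 19278, ranged over the alternatives from 16133 with a minimum of 2 FPKM to 20891 without a filter, and was 17625 at an adjusted p of 0.01. With a replicate block it was 19187; the replicate numbers do not pair the libraries, and no library correlated best with its own number. Higher genes numbered 8333 and lower genes 8464 with median-of-ratios scaling, and 7758 and 8899 with quantile normalisation, by construction of these scalings; genes differing by at least 1 on the log2 scale, 6691 in the main test, numbered 4440 and 4241 with these scalings, but 9386 with a pseudocount of 0.1 and 9314 with the same total FPKM. The median log2 difference, -0.56, was -0.69 with a pseudocount of 0.1, -0.26 without a filter, -0.61 with a minimum of 2 FPKM, -0.78 with the same total FPKM, -0.015 with median-of-ratios scaling and -0.044 with quantile normalisation. It was -0.33 on totals without the 100 most abundant genes, -0.13 without the 1000 most abundant, and between -0.56 and -0.55 when single libraries were left out. The miRNA families past the camera threshold, 0 in the main test, were 1 with a minimum of 2 FPKM, 4 with the same total FPKM, 3 with the replicate block, 6 with fry, and between 0 and 3 when single libraries were left out (2 without control replicate 2 and 3 without transgenic replicate 2); except for fry, which asks another question, the cause was not tested. The difference of zma-mir396a turned to 0.24 with median-of-ratios scaling and 0.21 with quantile normalisation. Over the 40 single genes examined, 525 values under alternatives kept direction and side of the threshold, 30 lost the call with the direction kept and 17 gained it. In 2 further values, those of zma-mir396a under median-of-ratios and quantile scaling, the call was lost and the sign turned. The sign also turned in 4 values of 3 genes called in neither setting (zma-mir160b, zma-mir169a and zma-mir396d). Among the genes named as changed, zma-mir156i, zma-mir393a and zma-mir396a lost their calls when certain single libraries were left out; zma-mir156i did so without control replicate 1 or 3 or transgenic replicate 1 or 3, and zma-mir396a without control replicate 3 or transgenic replicate 1 or 3. No value of ZmSUS1 or of the planned gene lists was computed, so their alternatives were not run. Read depth, which would limit the lowest genes, is unknown.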

Other observations

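The tests of abundant genes, replicate spread, miR156 scaling and copper-related genes in this part were chosen after the results were seen. The gene-wise limma tests and their alternatives, and the counts over other splits, were planned, though the miRNA genes named were chosen after their values were seen. When the miR172 test was written, it was known only that no such gene reached the minimum FPKM.

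Of the 154 miRNA genes in the files, 102 were listed at 0 in all 6 libraries. The auxin-receptor miRNA gene zma-mir393a averaged 0.99 ± 1.14 FPKM (SD, n = 3) in the control and 2.89 ± 0.73 FPKM (SD, n = 3) in the transgenic libraries (limma adjusted p = 0.021). The sulfate-related gene zma-mir395o averaged 1.07 ± 0.19 and 0.103 ± 0.179 FPKM (limma adjusted p = 0.00038). After median-of-ratios scaling the limma adjusted p of these genes was 0.0033 and 0.0034. The call of zma-mir393a was lost with a pseudocount of 0.1, without a filter, and when control replicate 2, transgenic replicate 1 or transgenic replicate 2 was left out.

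Most genes were lower in the transgenic libraries while a small number of abundant genes were higher. If those genes alone displaced the rest, totals without them should bring the median log2 difference to about 0. Without the 100 most abundant genes of either group the median was -0.33, and without the 1000 most abundant it was -0.13. The matching value, with all genes kept in totals scaled to be the same, was -0.78. As deposited, without such scaling, it was -0.56. Both values without abundant genes stayed beyond the limit of 0.1 that had been set for about 0. The displacement by abundant genes may therefore account for much of the shift. Whether it accounts for all of it cannot be told from these 2 chosen sizes, since the median still moved toward 0 from the first to the second. Relative values cannot tell a broad fall in other transcripts from a rise in total RNA of the abundant ones, which stays open.

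The number of changed genes was 19278 with the labelled groups. Of the 10 splits of the 6 libraries into 3 and 3, 1, the labelled one, gave as many. The highest of the others gave 0, and 10 splits are too few for a share under 0.05. Each of the other splits mixes the groups, so it would give few calls whatever caused the difference. The part of the variation between libraries that did not shrink with expression level had a coefficient of variation of 1.88% in the control and 1.34% in the transgenic libraries. This is consistent with replicates drawn from one RNA pool or from pooled plants in each group, a hypothesis the labels do not settle. Differences between single plants or growing positions would then enter the comparison together with the transgene, and both stay open.

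The lower miR156 level might come from the scaling or from leaves of an older developmental phase. The test of the family tried first, camera under median-of-ratios scaling, gave an adjusted p of 0.288, but camera gave no call as deposited either (adjusted p = 0.445, and 0.176 to 0.598 over its alternatives), so it decides nothing. With fry, chosen after that value was seen and asking only whether the genes moved one way, the adjusted p under that scaling was 0.00025. It rests on the same scaled values as the tests of single genes, and 7 of 10 families passed it, so it adds little. Under that scaling 5 of the 9 genes were still called lower, zma-mir156d at -2.57, so for these this scaling did not remove the difference. For 3 of the 8 called genes the call ended because the difference shrank, for zma-mir156e from -0.86 to -0.23, so for these scaling stays open. An older phase predicts higher miR172, but the 4 miR172 genes summed to 0.0 FPKM in every library, so a phase difference and an effect of the transgene, or of drought if the control plants had none, cannot be told apart.

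As a further hypothesis, the higher level of the tested miR398, miR408 and miR528 genes may reflect a response shared by the copper-related miRNAs. Summed over these tested genes, the level rose from 62.7 ± 3.8 to 162.8 ± 13.4 FPKM (SD, n = 3 each). The difference was 2.60-fold as deposited and 4.17-fold after median-of-ratios scaling. The remaining copper-related genes, those of miR397 and any miR408 gene below the minimum, 2 genes in all, were above every control library in 1 of 3 transgenic libraries. Their sums were 0, 1.75 and 0.84 FPKM in the control libraries and 0, 0 and 4.77 FPKM in the transgenic libraries. The value of 4.77 FPKM, of zma-mir397b, had been seen before the test was written. That gene did not pass the gene-wise test (limma adjusted p = 0.22), and the control values above 0 came from the other gene. The sums are too close to 0 to decide.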
